A study of Mus musculus with 37 samples.

How the data were processed

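Messenger and other long RNAs were measured by bulk RNA sequencing in gastrocnemius muscle of wild-type mice and of mice lacking Nampt in skeletal muscle, at 2, 4, 6 and 8 weeks of age. Per the labels, RNA was purified on RNeasy columns, ribosomal RNA was depleted, libraries were stranded, and 38-bp paired ends were sequenced. Each of the 37 libraries came from a numbered animal and from 1 of 2 sequencing pools, A and B. Sex was labelled at 4, 6 and 8 weeks and was not collected at 2 weeks.

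The deposited table holds counts per Ensembl gene, whole numbers with no normalization, for 50686 genes. The submitters' notes name STAR 2.5.2b, featureCounts 1.5.2, edgeR 3.22.0 and the mouse build mm10, without the role or order of each. The gene annotation, the strand setting and whether single reads or read pairs were counted are not stated, so values of genes that overlap another gene or have near-identical copies are uncertain. Gene symbols and positions were taken from GENCODE vM21 (GRCm38), in which 50376 of the 50686 identifiers had an entry.

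Total counts per library ran from 5192700 to 23134727, with a median of 16827002. Of the 50686 genes, 15977 had no count in any library, and 16728 passed edgeR's filterByExpr by group with a minimum count of 10 and a minimum total of 15. The genes left out held at most 0.134% of any library's counts. Libraries were scaled with TMM factors, which ran from 0.443 to 1.59. Counts scaled to a common library total (CPM) were computed with these factors and are given as mean ± SD over animals.

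All 37 libraries entered 1 model in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F-test, robust), with a term for each of the 8 genotype-by-age groups and a term for the sequencing pool. The common biological coefficient of variation was 0.189, with 28 residual degrees of freedom and a median of 6.96 prior degrees of freedom. Fold changes are log2 values of knockout over wild type with their standard error (SE), unless another comparison is named. A gene was called changed when its Benjamini-Hochberg adjusted p lay below 0.05 over all genes tested. Differences of the knockout effect between ages were tested as contrasts within the same model. Nampt was also tested with a two-sided exact permutation test of log2 CPM within each age and with a permutation test within age and pool over all ages.

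Before the data were examined, 36 gene lists, the tests, the alternatives and the rule for named genes were fixed. By that rule Nampt is always named. At each age the 12 largest rises and 12 largest falls are named among called genes with a mean log2 CPM of at least 1 and the same sign in both pools, and 6 each way, without the condition on pools, for differences between ages. Predicted genes, mitochondrial genes, pseudogenes and sex-linked marker genes are left out of the ranking. From each list described, up to 4 members with the smallest p are named, and any member needed to say what did not pass. The lists cover NAD synthesis and use, energy metabolism, mitochondria, stress, muscle fibre programs, regeneration, denervation, matrix, and markers of other cell types.

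Each list was tested against all other genes with camera in limma 3.58.1 on log2 CPM (prior count 2), with the correlation between genes preset at 0.01 and again with the correlation estimated from the residuals. Adjusted p-values of lists were taken over all lists and the 4 ages for the genotype effect, and over all lists within the other comparisons. Members were counted over all genes tested and adjusted over the list alone.

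The alternatives were RLE factors, library sizes without scaling factors, no filter on low counts, no pool term, each pool alone, only the groups compared, a sex term, males alone, DESeq2 1.42.0, and leaving out each library in turn. Further alternatives were chosen after seeing the data, namely leaving out the 5 libraries with over 5% of counts in nuclear rRNA genes, these together with wild-type animal 36, and the 3 libraries whose sex-linked genes differ from their label. The test was checked on simulated data, in which changes of 1 log2 unit were recovered for 76.1% of genes at the design of 2 weeks, 73.1% at 4 weeks, 29.9% at 6 weeks and 82.1% at 8 weeks. Sex was not labelled at 2 weeks, so the planned sex term covered 4 to 8 weeks, and it and the comparison of males used the labels. A sex term over all ages, taken from the counts (female where Xist exceeds Ddx3y), was added after seeing the data. Results of some genes are not reported here. No sample in the deposited table was left out of the main comparisons.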

Results

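Gene counts were available for 37 gastrocnemius libraries, 1 per animal, from wild-type mice and mice with a skeletal-muscle-specific knockout of Nampt, the rate-limiting enzyme of NAD salvage from nicotinamide. There were 6 wild-type and 5 knockout libraries at 2 weeks, 6 and 5 at 4 weeks, 2 and 2 at 6 weeks, and 5 and 6 at 8 weeks. Total counts ran from 14404387 to 19355063 in wild type and from 16827002 to 21888652 in knockout at 2 weeks. At 4 weeks they ran from 10795778 to 23134727 in wild type and from 6668855 to 20997634 in knockout. At 6 weeks they ran from 15930582 to 21437318 in wild type and from 14510798 to 19592059 in knockout. At 8 weeks they ran from 5192700 to 20122887 in wild type and from 13422624 to 20760973 in knockout. The first principal component of log2 CPM held 28.6% of the variance and the second held 22.3%.

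Several libraries stood apart from their group. Genes annotated as nuclear rRNA held 11.6% of counts in wild-type animal 3 and 8.49% in wild-type animal 4 at 4 weeks, 29.3% in knockout animal 8 at 4 weeks, and 20.3% and 23.1% in wild-type animals 34 and 35 at 8 weeks. The other libraries held at most 1.24%. Animals 34 and 35 were the only 8-week wild-type libraries of pool A, so 8-week values of pool A alone compare knockout with rRNA-rich libraries only. Without the rRNA-rich libraries the 8-week wild type lies in pool B alone. Wild-type animal 36 at 8 weeks carried 9293 CPM of Myh7, the slow myosin heavy chain, and 6596 CPM of Myh4, the fast type IIb chain. Knockout animals 12 (4 weeks) and 42 (8 weeks), labelled male, had 63.8 and 199 CPM of Xist, the RNA of the inactive X chromosome. Wild-type animal 4, labelled female, had 45.1 CPM of Xist and 66 counts (8.00 CPM) of the Y-linked gene Ddx3y.

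**Figure D1:**
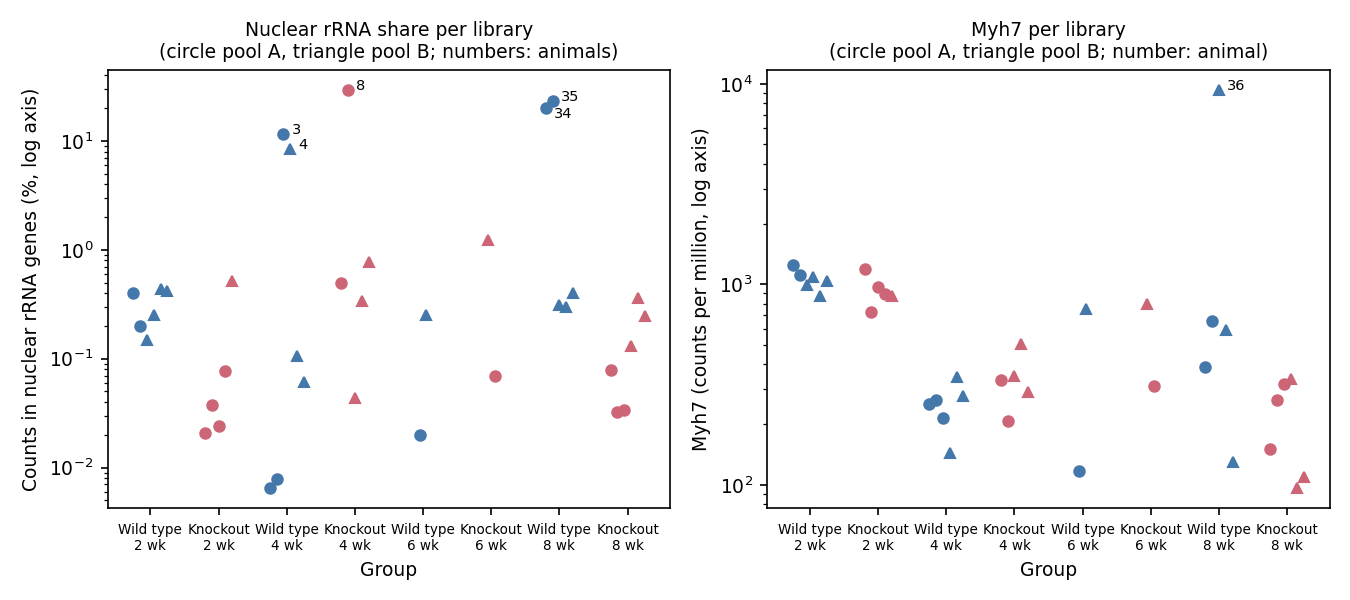
Share of counts in nuclear rRNA genes (left, percent, log axis) and Myh7 level (right, CPM, log axis) in each of the 37 libraries, with circles for pool A, triangles for pool B, blue for wild type and red for knockout. Animals 3, 4, 8, 34 and 35 lie above 5% rRNA, and animal 36 carries 9293 CPM of Myh7.

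Nampt RNA was lower in every knockout library than in every wild-type library of its age. Levels were 65.1 ± 9.32 CPM in wild type (SD, n = 6) and 33.1 ± 1.496 in knockout (n = 5) at 2 weeks, and 128 ± 19.8 (n = 6) and 62.8 ± 8.63 (n = 5) at 4 weeks. They were 210 ± 11.7 (n = 2) and 49.75 ± 2.5005 (n = 2) at 6 weeks, and 204 ± 27.5 (n = 5) and 49.3 ± 3.40 (n = 6) at 8 weeks. The knockout level was thus 50.8% of wild type at 2 weeks, 49.0% at 4 weeks, 23.7% at 6 weeks and 24.2% at 8 weeks. In wild type Nampt rose with age, by 0.99 log2 units from 2 to 4 weeks and by 0.67 from 4 to 8 weeks.

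The log2 fold change of Nampt (chromosome 12, 32819545 to 32853349, plus strand) was -0.96 (SE 0.11) at 2 weeks, -1.03 (SE 0.11) at 4 weeks, -2.07 (SE 0.18) at 6 weeks and -2.04 (SE 0.11) at 8 weeks. The edgeR adjusted p-values were 2.33e-06, 2.36e-07, 2.85e-09 and 7.36e-16. An exact permutation test gave p = 0.00216 at 2, 4 and 8 weeks, the smallest that 462 splits allow, and p = 0.333 at 6 weeks, the smallest that 6 splits allow. A permutation test within age and pool over all ages gave p = 1e-05, the smallest it can give. The counts sum all exons of the gene, and the deleted part is not in the labels. At 2 weeks the call was lost with library sizes alone (-0.79, adjusted p = 0.715 in edgeR), in pool A (-0.73, adjusted p = 0.888) and in pool B (-1.09, adjusted p = 0.170).

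**Figure D2:**
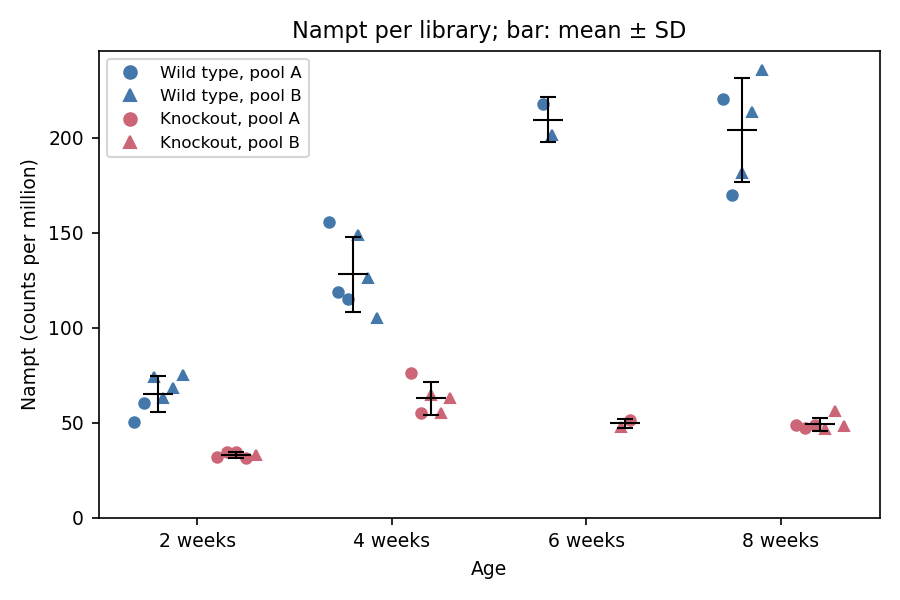
Nampt level (CPM) in each library by age, with blue for wild type, red for knockout, circles for pool A, triangles for pool B, and bars for mean ± SD. At 8 weeks the lowest wild-type library lies at 170 CPM and the highest knockout library at 56.0 CPM.

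The comparison at 2 weeks asks which genes had changed in young muscle. Ryr3, a ryanodine receptor of immature muscle, rose from 14.8 ± 1.42 CPM (n = 6) to 33.0 ± 5.49 (n = 5), a log2 fold change of 1.30 (SE 0.25). Acsl4, which activates long-chain polyunsaturated fatty acids, fell from 58.4 ± 4.17 to 37.6 ± 4.35 CPM, a log2 fold change of -0.59 (SE 0.11). Each lay beyond every wild-type library in 5 of 5 knockout libraries. Outside the rule for named genes, and chosen after their values were seen, Gm10800 rose by 7.24 log2 units, Gm10801 by 5.57, Gm21738 by 4.52, Gm5083 by 4.51 and Chrna9 by 1.65, while Vtcn1 fell by 3.03 and Rps6ka6 fell by 1.57. Of the 38-bp words of Gm10800, 36.6% also occur in other annotated genes, so its count is uncertain.

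By edgeR, 10 of 16728 genes changed at 2 weeks (6 rose, 4 fell), with 812 at an unadjusted p below 0.05 where 836.4 would be expected by chance, and DESeq2 called 20. The adjusted p was 0.0214 for Ryr3 and 0.0115 for Acsl4. Pool A alone gave 1 gene and pool B alone 2, the 2-week libraries alone gave 177, and 5 were called without wild-type animal 21. The Ryr3 call was lost when any of wild-type animals 21, 24, 25, 26 and 32 or knockout animals 22, 29 and 31 was left out, and the Acsl4 call without wild-type animal 21 or knockout animal 30. Ryr3 also lost it without the pool term, with no filter, with library sizes alone, in either pool and without the rRNA-rich libraries, and Acsl4 with library sizes alone and in either pool.

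Besides Nampt in the NAD synthesis list, no list member passed the test at 2 weeks over all genes. Lymphocyte markers had a median of 0.85 (camera adjusted p = 1.85e-07; adjusted p = 0.62 with an estimated correlation). Their mean log2 CPM was 0.76, 0.47 and 0.19 in knockout animals 28, 29 and 31 and 0.72 in wild-type animal 25, against -2.34 to -2.11 in the other 2-week libraries, knockout animals 22 and 30 among them. Extracellular matrix genes lay lower (median -0.25, camera adjusted p = 1.26e-07; adjusted p = 0.62 with an estimated correlation). So did Schwann cell and nerve markers (median -0.50, adjusted p = 4.86e-06; adjusted p = 0.62 with an estimated correlation). Cell cycle genes had a median of -0.49 (camera adjusted p = 1.92e-06; adjusted p = 0.648 with an estimated correlation). Fibroblast markers stood at -0.22 (adjusted p = 0.000112; adjusted p = 0.62 with an estimated correlation), and lipid and sterol synthesis at -0.27 (adjusted p = 0.00164; adjusted p = 0.62 with an estimated correlation). Knockout libraries lay on these sides of the wild-type mean in 3 of 5 for lymphocyte markers, 4 of 5 for cell cycle and 5 of 5 for the other 4 lists. The called lists of complex I (median 0.08, camera adjusted p = 0.00154), complexes III to V (0.09, adjusted p = 0.000112), fatty acid oxidation (0.16, adjusted p = 0.000257), macrophage markers (-0.23, adjusted p = 0.024) and the dystrophin complex (-0.077, turning to 0.087 with library sizes alone, adjusted p = 0.0323) lost their call without the pool term, as did cell cycle. Macrophage markers also lost it without any of wild-type animal 25 and knockout animals 22 and 29, and the dystrophin complex without any of wild-type animals 24 and 32 and knockout animals 28, 29 and 31. In order, the values of these 5 lists were adjusted p = 0.896, 0.737, 0.721, 0.90 and 0.62 with an estimated correlation. With library sizes alone the median of all genes stood at 0.13 at 2 weeks (-0.019 with TMM scaling). Adjusted over the list alone, Nampt and 2 higher genes passed in NAD synthesis, 1 fibroblast marker was lower, and 1 gene of mitochondrial calcium, pore and dynamics was higher.

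At 4 weeks Nmrk2, a muscle nicotinamide riboside kinase that makes NAD by a route that bypasses Nampt, rose from 23.4 ± 11.1 CPM (n = 6) to 378 ± 198 (n = 5). Its log2 fold change was 4.03 (SE 0.44), and 5 of 5 knockout libraries lay above every wild-type library. Pdk4, which inhibits pyruvate dehydrogenase, rose by 2.32 (SE 0.49) and Angptl4, an inhibitor of lipoprotein lipase, by 2.32 (SE 0.50). The metal-binding metallothioneins Mt2 (3.27, SE 0.86) and Mt1 (2.75, SE 0.70) rose, as did the macrophage genes Lgals3 (2.87, SE 0.54), Mpeg1 (2.73, SE 0.63) and Gpnmb (2.57, SE 0.68). Kcnq5, a potassium channel, fell by 1.63 (SE 0.18), Rnf128, a ubiquitin ligase, fell by 1.47 (SE 0.16), and Tspan8, a tetraspanin, fell by 2.33 (SE 0.38), each in 5 of 5 knockout libraries below every wild-type library.

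Further named rises at 4 weeks were Rrad (3.10, SE 0.70), Serpina3n (2.80, SE 0.60), Ankrd1 (2.35, SE 0.52) and Nr4a3 (2.35, SE 0.51). Further named falls were Mss51 (-2.56, SE 0.75), Mettl21e (-2.06, SE 0.36), Cd28 (-1.99, SE 0.30), Amy1 (-1.92, SE 0.26), Galnt5 (-1.60, SE 0.46), Fer1l6 (-1.52, SE 0.26), the myosin heavy chain Myh13 (-1.51, SE 0.34), the sodium channel Scn2a (-1.47, SE 0.36) and Lrp2bp (-1.45, SE 0.43). All 12 named falls lay below every wild-type library in 5 of 5 knockout libraries. Mt2, the metallothionein, lay above every wild-type library in 3 of 5. Without the 5 rRNA-rich libraries 3 of the 12 named rises (Nmrk2, Lgals3, Serpina3n) and 8 of the 12 named falls kept their call. The numbers kept were 7 and 7 with library sizes alone, 12 and 9 with no filter, 6 and 9 without the 3 libraries that differ from their sex label, and 11 and 11 in pool A. They were 12 and 12 with sex taken from Xist and Ddx3y over all ages, 2 and 7 with the labelled sex at 4 to 8 weeks, 1 and 11 with the 4-week libraries alone, 1 and 3 in labelled males, and 0 and 3 in pool B.

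Macrophage markers rose in 7 of 23 members at 4 weeks, and in 17 adjusted over the list alone, with Lgals3, Mpeg1, Gpnmb and the lysosomal marker Cd68 (1.96, SE 0.49) among them. Their median was 1.01 (camera adjusted p = 6.42e-09; adjusted p = 0.62 with an estimated correlation), 3 of 5 knockout libraries lay above the wild-type mean, and 1 member was called without the rRNA-rich libraries. Atrophy and ubiquitin ligase genes rose in 7 of 21 (13 adjusted over the list alone), including Fbxo32, the muscle atrophy ligase atrogin-1 (2.12, SE 0.48), and Foxo3, a transcription factor of the atrophy program (0.42, SE 0.11). The median of that list was 0.42 (camera adjusted p = 2.71e-05; adjusted p = 0.62 with an estimated correlation), with 4 of 5 knockout libraries above the wild-type mean and 1 member called without the rRNA-rich libraries. Oxidative stress genes rose in 7 of 24 (9 adjusted over the list alone), including Srxn1, which reduces oxidised peroxiredoxins (1.64, SE 0.34), Nqo1, a quinone reductase (1.44, SE 0.36), and Ucp2 (1.13, SE 0.24). That list had a median of 0.16 (camera adjusted p = 3.47e-05; adjusted p = 0.62 with an estimated correlation), 5 of 5 knockout libraries above the wild-type mean, and no member called without the rRNA-rich libraries. Fibroblast markers fell in 3 of 13 (7 adjusted over the list alone), with Cd55 at -1.43 (SE 0.23) and Smoc2 at -0.58 (SE 0.14). Their median was -0.42 (camera adjusted p = 0.00019; adjusted p = 0.62 with an estimated correlation), below the wild-type mean in 5 of 5, and without the rRNA-rich libraries it was -0.27 with 1 member called.

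The number of called members at 4 weeks moved with single libraries. For macrophage markers it was 2 to 4 without any of wild-type animals 1, 2 and 3 and knockout animals 7, 8 and 12, and 14 and 12 without knockout animals 10 and 11. For atrophy genes it was 2 to 4 without any of wild-type animals 1 and 2 and knockout animals 7, 8 and 12, and 11 without knockout animal 10 or 11. For oxidative stress genes it was 3 or 4 without any of wild-type animals 1, 2 and 3 and knockout animals 7, 8 and 12. For fibroblast markers it was 1 without knockout animal 7 or 8 and 5 without knockout animal 11. The smaller shifts below had 1 to 5 rises over these omissions in inflammatory signalling, 0 to 4 in the integrated stress response and 0 to 6 in p53 targets, and 1 to 3 falls in calcium handling and 0 to 8 in extracellular matrix. The highest of these counts came without knockout animal 10 or 11. List medians at 4 weeks were larger in size in pool A than in pool B. They were 1.97 and 0.35 for macrophage markers, 1.03 and 0.15 for atrophy genes and 0.43 and 0.14 for oxidative stress. They were -0.64 and -0.24 for fibroblast markers, 0.77 and 0.22 for inflammatory signalling, 0.57 and 0.06 for the integrated stress response and 0.63 and 0.01 for p53 targets. Fatty acid oxidation had 0.21 and 0.18.

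Smaller shifts were called at 4 weeks in fatty acid oxidation (3 of 31 rose, median 0.20, camera adjusted p = 0.00428; adjusted p = 0.872 with an estimated correlation) and inflammatory signalling (2 of 23 rose, 4 adjusted over the list alone, median 0.48, adjusted p = 0.00735; adjusted p = 0.65 with an estimated correlation). Muscle calcium handling had 1 of 25 lower and a median of -0.25 (camera adjusted p = 0.0117; adjusted p = 0.705 with an estimated correlation). Of the integrated stress response 1 of 30 rose, Eif4ebp1, a repressor of translation (0.62, SE 0.17), at a median of 0.23 (camera adjusted p = 0.0141; adjusted p = 0.62 with an estimated correlation). Of 30 extracellular matrix genes 2 rose and 1 fell, and 2 and 7 adjusted over the list alone, at a median of -0.17 (camera adjusted p = 0.0233; adjusted p = 0.888 with an estimated correlation). Of 19 p53 targets 3 rose, at a median of 0.25 (camera adjusted p = 0.0432; adjusted p = 0.62 with an estimated correlation). Complex I had no called member of 36 and a median of -0.14 (camera adjusted p = 0.0117; adjusted p = 0.946 with an estimated correlation). Without knockout animal 8 the call of complex I was lost (-0.00305), as were those of inflammatory signalling and the integrated stress response. Complex I also lost it without wild-type animal 6, and p53 targets lost it without any of wild-type animals 1, 2, 3 and 5 and knockout animals 7 and 8. Without the rRNA-rich libraries complex I (camera adjusted p = 0.552), the integrated stress response (0.0778), inflammatory signalling (0.106) and p53 targets (0.143) lost their call, and fatty acid oxidation kept it with 0 of 31 members called. The p53 targets also lost it without the pool term. The call of fatty acid oxidation was lost without knockout animal 12 and without the 3 libraries that differ from their sex label, and that of extracellular matrix without knockout animals 7 or 10 or wild-type animals 2 or 6. Lymphocyte markers, at a median of 3.17, were not called (camera adjusted p = 0.0508) and lay above every wild-type library in 1 of 5 knockout libraries.

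At 4 weeks 946 of 16728 genes changed in edgeR, of which 412 rose (179 by more than 2-fold) and 534 fell (79 by more than 2-fold). The count moved to 303 without the 5 rRNA-rich libraries, 277 of them among the 946, to 97 with the labelled sex as a term at 4 to 8 weeks, to 9 in pool B, and to 120 with library sizes alone, of which 82 rose and 38 fell. With sex taken from Xist and Ddx3y over all ages it was 929. Leaving out 1 library moved it to 345 (knockout animal 7), 472 (knockout 8), 1598 (knockout 10), 548 (knockout 12), 505 (wild-type 1) and 601 (wild-type 2).

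At 6 weeks genes of immature muscle rose in the knockout. The perinatal myosin heavy chain Myh8 rose from 8.35 ± 0.896 CPM (n = 2) to 182 ± 115 (n = 2), a log2 fold change of 4.55 (SE 0.66), and the embryonic myosin heavy chain Myh3 from 7.66 ± 1.51 to 77.2 ± 11.7 CPM (3.36, SE 0.78). The fetal growth factor Igf2 rose by 3.36 (SE 0.60), and Sln, which inhibits the sarcoplasmic reticulum calcium pump, by 4.20 (SE 1.19). Macrophage genes rose too, with Gpnmb at 5.67 (SE 1.08), Lgals3 at 3.96 (SE 0.83) and the protease Ctss at 3.21 (SE 0.80). Amd1, the decarboxylase that supplies aminopropyl groups to polyamines, fell by 4.03 (SE 0.73), and Smox, which oxidises spermine, fell by 4.05 (SE 0.81).

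The other named rises at 6 weeks were the angiotensin receptor Agtr2 (5.21, SE 0.81), Atp1b4 (3.76, SE 0.39), the imprinted gene Rtl1 (3.72, SE 0.51), Mpeg1 (3.61, SE 0.95) and Shisal1 (3.44, SE 0.57). The other named falls were Rasd2 (-4.14, SE 0.96), the muscle-secreted peptide Ostn (-3.74, SE 0.39), Tspan8 (-3.43, SE 0.64), Myh13 (-2.91, SE 0.63), the cadherin Cdh4 (-2.90, SE 0.81), Amy1 (-2.83, SE 0.40), Barx2 (-2.82, SE 0.62), Neto2 (-2.54, SE 0.62), Mettl21e (-2.40, SE 0.54) and the potassium channel subunit Kcng4 (-2.38, SE 0.60). All 24 lay beyond both wild-type libraries in 2 of 2 knockout libraries. Without knockout animal 20, Gpnmb, Lgals3, Mpeg1, Ctss, Myh3, Sln and 8 of the 12 falls, Smox among them, lost their call. Without wild-type animal 16 the same 6 rises and 5 falls lost it, Smox again among them. Without wild-type animal 17 Ctss, Mpeg1, Myh3, Sln, Cdh4 and Myh13 lost it, and without knockout animal 19 Cdh4, Neto2 and Rasd2. With the 6-week libraries alone Gpnmb, Lgals3, Mpeg1, Ctss and Smox lost it, with the labelled sex as a term Sln, Cdh4, Kcng4 and Neto2, with library sizes alone Myh3, Sln and Barx2, and with no filter Sln.

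Nuclear genes of complex I, the entry of electrons into the respiratory chain, fell in 7 of 36 (21 adjusted over the list alone), including Ndufs1 (-0.71, SE 0.17) and Ndufa10 (-0.64, SE 0.19). Their median was -0.48 (camera adjusted p = 1.98e-10; adjusted p = 0.634 with an estimated correlation). The TCA cycle list fell in 4 of 26 (7 adjusted over the list alone), with Pdha1, a pyruvate dehydrogenase subunit, at -0.71 (SE 0.17) and a median of -0.39 (camera adjusted p = 1.09e-06; adjusted p = 0.62 with an estimated correlation). Complexes III to V fell in 2 of 38 (0 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 3.66e-07; adjusted p = 0.652 with an estimated correlation). Mitochondrial chaperones and proteases fell in 3 of 15, at a median of -0.28 (camera adjusted p = 0.00109; adjusted p = 0.62 with an estimated correlation). Glycolysis fell in 3 and rose in 1 of 28, at -0.47 (adjusted p = 0.00183; adjusted p = 0.652 with an estimated correlation). In each of these 5 lists 2 of 2 knockout libraries lay below both wild-type libraries.

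Myogenesis and regeneration genes rose in 6 of 23 at 6 weeks (7 adjusted over the list alone, with 2 lower), including Myh8, Myh3, Igf2 and Dlk1, an imprinted regulator of differentiation (2.78, SE 0.61). Their median was 0.65 (camera adjusted p = 9.43e-05; adjusted p = 0.62 with an estimated correlation). Macrophage markers rose in 9 of 23 (14 adjusted over the list alone), with Trem2, a lipid receptor, at 3.80 (SE 0.73), and a median of 1.56 (camera adjusted p = 4.92e-06; adjusted p = 0.648 with an estimated correlation). Inflammatory signalling rose in 2 of 23, at 0.52 (camera adjusted p = 0.0117; adjusted p = 0.652 with an estimated correlation). Fibroblast markers fell in 4 of 13, with the matrix proteoglycan Dcn at -1.27 (SE 0.26). Their median was -0.38 (camera adjusted p = 0.00455; adjusted p = 0.62 with an estimated correlation). Endothelial markers fell in 1 of 13, the water channel Aqp1 (-1.26, SE 0.21), at a median of -0.44 (camera adjusted p = 0.00127; adjusted p = 0.648 with an estimated correlation). Leaving out any of the 4 libraries lowered the called members to 0 to 2 for complex I and for the TCA cycle and to 0 for complexes III to V, and chaperones had 0 or 1 and glycolysis 0 to 2. More fell without the rRNA-rich libraries, all of other ages: 12 in complex I, 7 in the TCA cycle and 8 in complexes III to V, and without these and animal 36 20, 9 and 10, with 7 in glycolysis. Macrophage markers ran from 0 (without wild-type animal 16 or knockout animal 20) over 5 (without wild-type animal 17) to 14 (without knockout animal 19). Myogenesis had 3 without wild-type animal 16 or 17 and 2 without knockout animal 20, and fibroblast markers 1 without wild-type animal 16 or knockout animal 20. The calls of macrophage markers, glycolysis and chaperones were lost without knockout animal 20, and that of inflammatory signalling without knockout animal 19 or wild-type animal 16.

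At 6 weeks 1617 genes changed in edgeR, of which 891 rose (609 by more than 2-fold) and 726 fell (226 by more than 2-fold). With 2 libraries per group the spread is borrowed from the other ages, and the 6-week libraries alone gave 584. The count was 330 with library sizes alone (238 rose, 92 fell), 615 with the labelled sex as a term, 1535 with sex taken from Xist and Ddx3y, 244 without wild-type animal 16, 522 without wild-type 17 and 286 without knockout 20. In 30 draws of 2 libraries per genotype, 1 from each pool, from each other age, counts were tested within that age. The median count was 137.5 at 2 weeks (1 to 1103), 2.5 at 4 weeks (0 to 267) and 3335 at 8 weeks (103 to 5937). Every 2-week draw held knockout animal 31, and every 8-week draw held rRNA-rich wild-type animal 34 or 35. The draws are thus a rough yardstick for 6 weeks and do not rank the other ages.

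At 8 weeks genes of embryonic and regenerating muscle were among the named rises. Mymk, the membrane protein that fuses myoblasts, rose from 0.332 ± 0.325 CPM (n = 5) to 24.96 ± 17.1 (n = 6), a log2 fold change of 6.51 (SE 0.57). Myh8 rose from 6.46 ± 2.76 to 354 ± 248 CPM (5.81, SE 0.46), Myh3 from 13.4 ± 14.99 to 420 ± 300 CPM (4.89, SE 0.52), and Myl4, an embryonic myosin light chain, by 4.51 (SE 0.36). Macrophage genes rose, with Lgals3 at 4.89 (SE 0.55), Mpeg1, a pore-forming protein of phagocytes, at 4.55 (SE 0.63) and Ms4a7 at 4.35 (SE 0.39). Amd1, the polyamine enzyme, fell from 385 ± 300 to 24.1 ± 6.38 CPM (-3.97, SE 0.43). Amy1, an amylase, fell by 3.72 (SE 0.24).

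The other named rises at 8 weeks were Mt2 (5.25, SE 1.08), Agtr2 (5.09, SE 0.69), Shisal1 (5.04, SE 0.45), Mt3 (4.44, SE 0.35) and Igf2 (4.39, SE 0.40). All 12 rises lay above every wild-type library in 6 of 6 knockout libraries. Among the named falls were Rp1 (-5.30, SE 0.68), Cdh4 (-4.20, SE 0.51), the homeobox gene Barx2 (-3.74, SE 0.40), Myh13 (-3.72, SE 0.38) and Efcab6 (-3.36, SE 0.20). Cdh4 lay below every wild-type library in 3 of 6 knockout libraries, and the other 4 genes in 6 of 6. Rp1 lost its call in pool A. The remaining 5 named falls, Lars2 (-7.91, SE 2.43), CT010467.1 (-7.42, SE 2.34), Mir6236 (-6.27, SE 2.04), Mir6240 (-5.95, SE 1.51) and n-R5-8s1 (-4.36, SE 1.48), moved with the rRNA share. Without the rRNA-rich libraries their values were -1.79 (adjusted p = 0.226 in edgeR), -1.08 (0.297), -1.005 (0.413), -1.10 (0.430) and -1.57 (0.101), and their calls were lost.

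**Figure D3:**
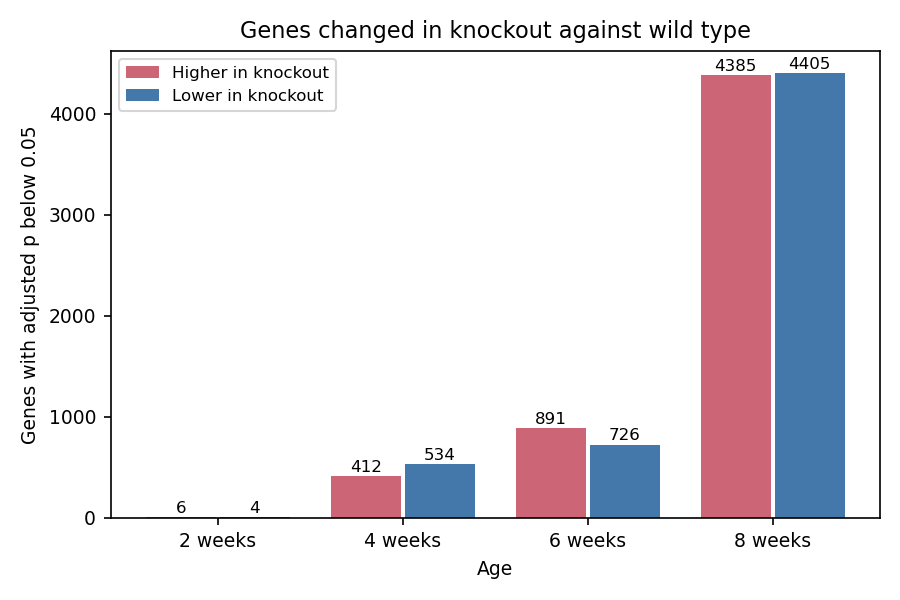
Number of genes (vertical axis, genes with an edgeR adjusted p below 0.05 of 16728 tested) higher (red) and lower (blue) in knockout than in wild type at each age. The bars stand at 6 and 4 genes at 2 weeks, 412 and 534 at 4 weeks, 891 and 726 at 6 weeks, and 4385 and 4405 at 8 weeks, the last split being 10718 and 501 with library sizes alone.

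Macrophage markers rose in 23 of 23 at 8 weeks, with the complement genes C1qb (2.85, SE 0.25) and C1qc (2.30, SE 0.21) and the receptor Trem2 (5.67, SE 0.58). Their median was 2.97 (camera adjusted p = 2.9e-13; adjusted p = 0.62 with an estimated correlation). Cell cycle genes rose in 24 of 26, including the mitotic kinases Cdk1 (3.54, SE 0.54) and Bub1b (2.98, SE 0.42). Their median was 2.501 (camera adjusted p = 9.81e-09; adjusted p = 0.62 with an estimated correlation). Inflammatory signalling rose in 20 of 23, including the chemokine Ccl8 (4.94, SE 0.52). Their median was 1.35 (camera adjusted p = 2.21e-06; adjusted p = 0.62 with an estimated correlation). Extracellular matrix genes rose in 20 of 30, including the collagens Col3a1 (1.71, SE 0.21) and Col6a3 (1.47, SE 0.17) and the growth factor Tgfb1 (2.02, SE 0.24). Their median was 0.85 (camera adjusted p = 1.47e-06; adjusted p = 0.62 with an estimated correlation). In each of these 4 lists 6 of 6 knockout libraries lay above every wild-type library.

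Myogenesis and regeneration genes rose in 19 and fell in 1 of 23 at 8 weeks, including Myog, a transcription factor of muscle differentiation (3.35, SE 0.32), and Ncam1, an adhesion molecule (2.27, SE 0.26). Their median was 1.58 (camera adjusted p = 1.26e-07; adjusted p = 0.62 with an estimated correlation). Genes that respond to denervation rose in 16 and fell in 1 of 22, including Chrng, the fetal subunit of the muscle acetylcholine receptor (6.08, SE 0.57), and Chrna1, its alpha subunit (2.10, SE 0.21). Their median was 0.96 (camera adjusted p = 9.43e-05; adjusted p = 0.152 with an estimated correlation), and in both lists 6 of 6 knockout libraries lay above every wild-type library. Schwann cell and nerve markers fell in 9 and rose in 1 of 12, including Prx, a protein of myelinating Schwann cells (-1.74, SE 0.31), and Sox10, a transcription factor of the glial lineage (-1.69, SE 0.30). Their median was -1.71 (camera adjusted p = 0.00327; adjusted p = 0.652 with an estimated correlation), lower than the wild-type mean in 6 of 6. Without the rRNA-rich libraries and animal 36 the median was -1.02 and the call was lost (camera adjusted p = 0.0796).

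Lists of energy metabolism lay lower in the knockout at 8 weeks, in 6 of 6 knockout libraries below the wild-type mean. Medians with library sizes alone are given beside those with TMM scaling, and include the rRNA-rich wild-type animals 34 and 35. The TCA cycle list fell in 25 of 26, including the succinyl-CoA ligase subunit Suclg2 (-1.19, SE 0.10) and Pdha1 (-0.84, SE 0.11). Its median was -0.67 that turned to 0.18 with library sizes alone (camera adjusted p = 1.58e-09; adjusted p = 0.62 with an estimated correlation). Complex I fell in 33 of 36, including Ndufa1 (-1.03, SE 0.12) and Ndufs1 (-0.87, SE 0.11). Its median was -0.62 that turned to 0.19 (camera adjusted p = 5.01e-10; adjusted p = 0.641 with an estimated correlation). Complexes III to V fell in 33 and rose in 2 of 38, including Cox6a2, a muscle subunit of cytochrome oxidase (-1.23, SE 0.13). Its median was -0.50 that turned to 0.31 (camera adjusted p = 2.43e-07; adjusted p = 0.652 with an estimated correlation). Messenger RNAs encoded by mitochondrial DNA fell in 8 of 8, including mt-Nd1 (-2.09, SE 0.30). Their median was -1.52, and -0.69 with library sizes alone (camera adjusted p = 0.00107; adjusted p = 0.62 with an estimated correlation). It was -2.46 in pool A and -0.80 in pool B, and the rRNA-rich wild-type animals 34 and 35 had the highest mean log2 CPM of the age (11.4 and 10.7, other wild-type animals 9.36 to 10.4). Of the 8, 6 fell without the rRNA-rich libraries (-1.19) and 5 without these and animal 36 (-1.09). Fatty acid oxidation fell in 21 and rose in 2 of 31, including Lpl, lipoprotein lipase (-1.74, SE 0.23), and Acadm, an acyl-CoA dehydrogenase (-1.14, SE 0.15). Its median was -0.72 that turned to 0.07 (camera adjusted p = 0.000112; adjusted p = 0.705 with an estimated correlation). Wild-type animal 36 had a mean log2 CPM of 7.16 in fatty acid oxidation, against 6.04 to 6.38 in the other 8-week wild-type animals. Without it 17 genes of fatty acid oxidation fell, at a median of -0.51 (camera adjusted p = 0.003). Regulators of mitochondrial biogenesis fell in 9 of 18, including the nuclear receptor Ppara (-1.60, SE 0.22). Their median was -0.41 that turned to 0.43 (camera adjusted p = 0.00223; adjusted p = 0.62 with an estimated correlation). Chaperones and proteases of mitochondria fell in 11 and rose in 2 of 15, at a median of -0.41 that turned to 0.41 (camera adjusted p = 0.00633; adjusted p = 0.648 with an estimated correlation). Glycolysis and glycogen fell in 13 and rose in 4 of 28, at a median of -0.50 that turned to 0.35 (camera adjusted p = 0.0326; adjusted p = 0.806 with an estimated correlation). That call was lost without wild-type animals 34, 35, 37 or 38 or knockout animals 39 or 40, and without the rRNA-rich libraries. It was kept without wild-type animal 36, where 19 fell at a median of -0.60 (camera adjusted p = 0.00021). Without the rRNA-rich libraries and animal 36 together the median was -0.61 (camera adjusted p = 0.00164). The mean log2 CPM of animal 36 was 7.94, against 8.79 to 8.87 in the other 8-week wild-type animals.

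Contractile and excitation genes lay lower too. Muscle calcium handling fell in 18 and rose in 2 of 25, including Cacna1s, the calcium channel of the T-tubule (-1.23, SE 0.15), and Stac3, its adaptor (-1.38, SE 0.15). Its median was -0.76 that turned to 0.10 with library sizes alone (camera adjusted p = 0.000249; adjusted p = 0.64 with an estimated correlation). Fast fibre genes fell in 15 of 17, including Actn3, a fast-fibre actinin (-1.39, SE 0.32). Their median was -0.82 that turned to 0.03 (camera adjusted p = 0.00118; adjusted p = 0.692 with an estimated correlation). Without wild-type animal 36, 16 of 17 fell, and without the rRNA-rich libraries 10. Slow fibre genes fell in 10 and rose in 1 of 14 (7 and 3 without animal 36), and the list was not called (camera adjusted p = 0.116). Their median of -1.77 was -0.33 without animal 36, whose mean log2 CPM of 9.63 stood against 5.87 to 6.86 in the other wild-type animals. Endothelial markers fell in 12 of 13, including the receptors Tek (-0.95, SE 0.13) and Flt1 (-0.90, SE 0.13). Their median was -0.54 that turned to 0.27 with library sizes alone (camera adjusted p = 0.000918; adjusted p = 0.648 with an estimated correlation). Erythroid markers fell in 5 of 7, including the globin genes Hba-a1 (-1.67, SE 0.32) and Hbb-bs (-1.31, SE 0.26). Their median was -1.24 (camera adjusted p = 0.0302; adjusted p = 0.692 with an estimated correlation). That call was lost without wild-type animal 36 or knockout animal 43. Each of these 5 lists lay below the wild-type mean in 6 of 6 knockout libraries, but without animal 36 slow fibre genes did so in 4 of 6 and erythroid markers in 5 of 6.

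NAD synthesis genes changed in both directions at 8 weeks, with 5 of 11 higher and 5 lower, and the list was not called (camera adjusted p = 0.708). Without the rRNA-rich libraries 2 were higher and 4 lower. There were 3 higher without wild-type animal 34, and 3 higher and 3 lower without wild-type animal 37 or knockout animal 44. Nmrk2, the nicotinamide riboside kinase, rose by 1.98 (SE 0.42). Genes of NAD consumption and transport rose in 5 and fell in 6 of 19 (camera adjusted p = 0.748), with the deacetylase Sirt2 at -0.77 (SE 0.09), which turned to 0.10 with library sizes alone. The integrated stress response had 16 higher and 6 lower of 30 (median 0.68, camera adjusted p = 0.0655), p53 targets 10 and 4 of 19 (0.66, adjusted p = 0.148) with the cell cycle inhibitor Cdkn1a at 2.24 (SE 0.43), and oxidative stress genes 12 and 6 of 24 (0.44, adjusted p = 0.255) with the mitochondrial superoxide dismutase Sod2 at -1.08 (SE 0.09).

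Other lists not called by camera at 8 weeks were mitochondrial calcium, pore and dynamics (8 higher and 11 lower of 24, adjusted p = 0.18), where the fusion gene Mfn1 fell by 1.33 (SE 0.09), atrophy and ubiquitin ligases (5 and 6 of 21, adjusted p = 0.886), and autophagy and lysosome (7 and 9 of 22, adjusted p = 0.627). The same held for the dystrophin complex and membrane repair (7 and 8 of 22, adjusted p = 0.852), fibroblast markers (4 and 3 of 13, adjusted p = 0.951), neutrophil markers (1 and 0 of 8, adjusted p = 0.587) and lymphocyte markers (3 and 0 of 16, adjusted p = 0.587). It also held for smooth muscle and pericyte markers (2 and 6 of 11, adjusted p = 0.0836), adipocyte markers (0 and 7 of 12, adjusted p = 0.208), circadian clock genes (1 and 8 of 19, adjusted p = 0.0811) and lipid and sterol synthesis (3 and 7 of 20, adjusted p = 0.382). Without wild-type animal 36 the adipocyte markers had 1 lower, fibroblast markers 6 lower, lipid synthesis 6 higher and the circadian list 11 lower, and the circadian list was then called (camera adjusted p = 0.0166). Adipocyte markers had 4 lower without knockout animal 39, neutrophil markers 2 higher without the same animal, and lymphocyte markers 1 higher without knockout animal 39 or 44. Mitochondrial calcium, pore and dynamics had 5 higher without any of wild-type animals 35, 37 and 38, and autophagy 4 higher without wild-type animal 34 or 35. Without the rRNA-rich libraries these 2 lists had 5 and 3 higher.

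Counts adjusted over the list alone at 8 weeks differed from these in extracellular matrix and inflammatory signalling (21 higher in each), the integrated stress response (17 higher), p53 targets (11 higher), lymphocyte markers (2 higher), fibroblast markers (4 lower), smooth muscle (7 lower) and mitochondrial calcium, pore and dynamics (13 lower).

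At 8 weeks 8790 of 16728 genes (52.5%) changed in edgeR, of which 4385 rose (2125 by more than 2-fold) and 4405 fell (1150 by more than 2-fold). Pool A alone, where the wild type was the rRNA-rich animals 34 and 35, gave 4286. With library sizes alone the median of all genes moved to 0.82 and the split to 10718 higher and 501 lower, so directions at 8 weeks are relative to the median of all genes. Of the 8790 genes, 2766 (31.5%) changed sign with library sizes alone, and 0 changed sign relative to that median. The 0 follows from the method, since a change of scaling moves all genes by nearly the same amount, and is no evidence on direction. The rRNA-rich wild-type animals 34 and 35 had TMM factors of 0.443 and 0.484. The other 8-week wild-type animals had 0.883 to 1.08, and the 8-week knockout animals 1.22 to 1.59. Library sizes alone were not tried without animals 34 and 35, so their share in the changes of sign at 8 weeks is not known.

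**Figure D4:**
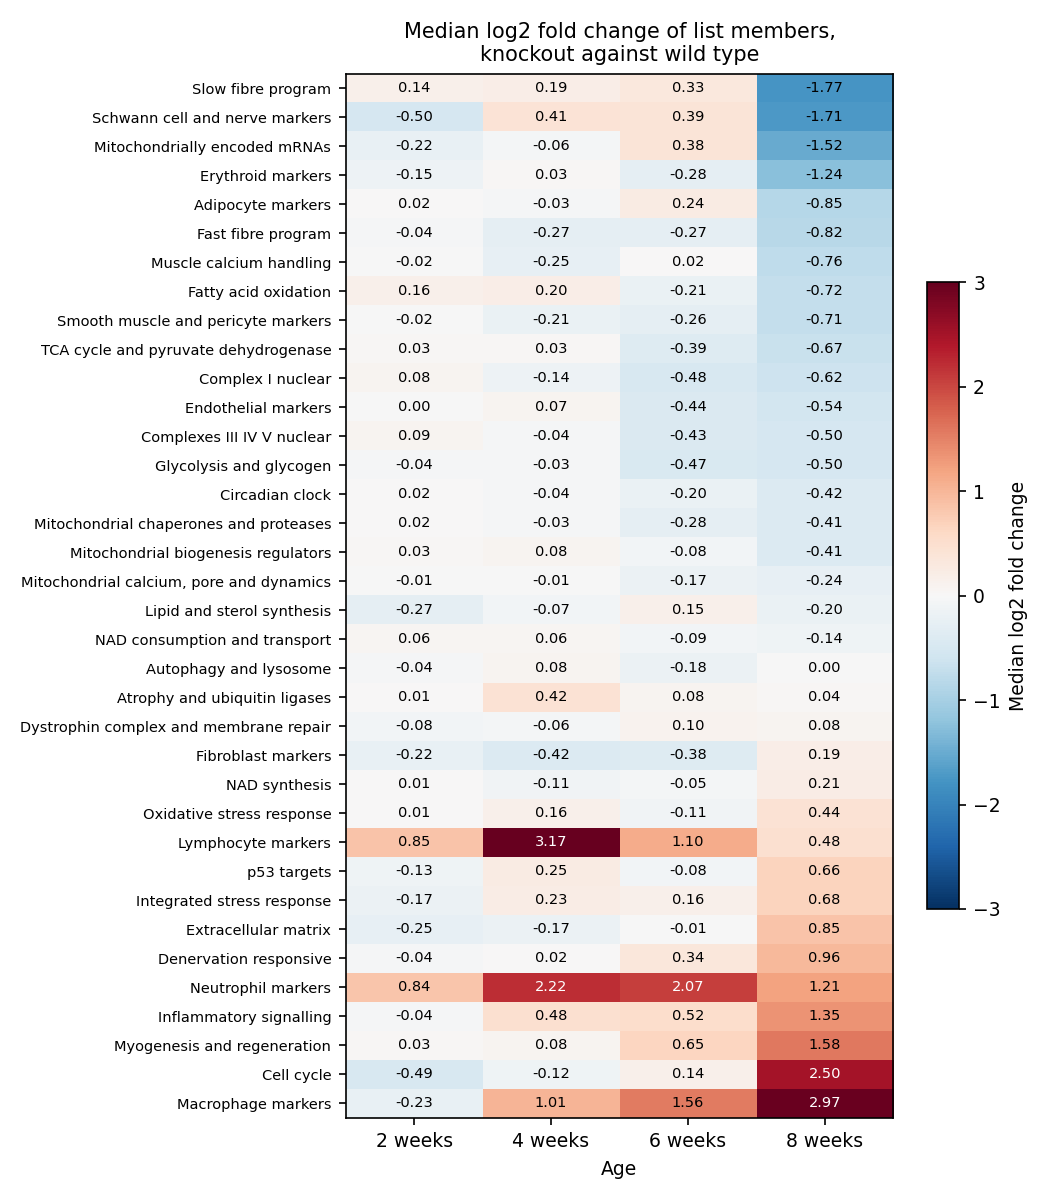
Median log2 fold change, knockout against wild type with TMM scaling, of the members of each of the 36 gene lists (vertical axis) at each age (horizontal axis), red for higher and blue for lower in knockout. At 8 weeks macrophage markers stand at 2.97 and cell cycle genes at 2.501, while every list from -0.82 up to 0 at 8 weeks turns above 0 with library sizes alone.

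Whether the knockout effect differed between ages was tested directly. From 4 to 8 weeks the effect on Mymk rose by 5.78, on Myh8 by 5.45, on Agtr2 by 4.99, on Shisal1 by 4.65, on Myl4 by 4.35 and on C1qtnf3, a secreted C1q-related protein, by 4.34. From 2 to 8 weeks it rose by 6.56 for Mymk, 5.41 for Myh8, 5.28 for Shisal1, 5.23 for Agtr2, 5.04 for Mt2 and 4.94 for Ms4a7. The effect on Nampt itself differed by -1.02 between 8 and 4 weeks and by -1.09 between 8 and 2 weeks. The falls from 4 to 8 weeks were in Rp1 (-4.47), Chac1, an enzyme that degrades glutathione (-3.76), and the rRNA-related Lars2 (-8.96), CT010467.1 (-8.76), Mir6236 (-7.69) and Mir6240 (-7.69). Lars2, CT010467.1 and Mir6236 lost this call in pool A, in pool B, in labelled males, with no filter, with the labelled sex as a term and with the groups of these 2 ages alone. They also lost it without wild-type animal 34 or any of knockout animals 8, 39 and 40, CT010467.1 and Mir6236 without knockout animal 41, and CT010467.1 without wild-type animal 2 or 35. Mir6240 lost it in pool B (-1.96), in labelled males, without wild-type animal 34, and without the rRNA-rich libraries and animal 36. In pool B the values of CT010467.1 (2.35) and Mir6236 (0.13) turned positive. Without the rRNA-rich libraries the 4 values were -6.39, -4.92, -5.45 and -4.99, and the calls were kept. Chac1 lost its call in either pool, and Rp1, Mymk and Agtr2 in pool A. From 2 to 8 weeks the falls were in Rp1 (-5.36), Cdh4 (-4.05), Myh13 (-3.96), Amd1 (-3.94), Mss51 (-3.83) and Barx2 (-3.70). From 2 to 8 weeks Mt2 lost its call in either pool, Agtr2, Mss51 and Rp1 in pool A, and Amd1 and Cdh4 in pool B.

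Between 8 and 4 weeks the effect grew for genes that respond to denervation, higher in 12 and lower in 1 of 22 (median 1.05, camera adjusted p = 1.17e-06), and between 8 and 2 weeks in 14 and 1 of 22 (0.95, adjusted p = 3.06e-05). These were the list differences called with an estimated correlation too (adjusted p = 0.00657 between 8 and 4 weeks and 0.0301 between 8 and 2 weeks). Macrophage markers differed between 8 and 4 weeks in 15 of 23 (median 2.02, camera adjusted p = 8.04e-11; adjusted p = 0.325 with an estimated correlation). Cell cycle genes differed in 22 of 26 (2.61, adjusted p = 1.26e-09; adjusted p = 0.36 with an estimated correlation). Extracellular matrix genes differed in 19 of 30 (1.27, adjusted p = 3.89e-11; adjusted p = 0.289 with an estimated correlation). The TCA cycle list differed the other way in 22 of 26 (-0.63, turning to 0.15 with library sizes alone, camera adjusted p = 2.31e-12; adjusted p = 0.289 with an estimated correlation). Fatty acid oxidation did so in 22 of 31 with 1 against (-0.91, and -0.19 with library sizes alone, adjusted p = 3.3e-09; adjusted p = 0.36 with an estimated correlation). Atrophy and ubiquitin ligase genes had a smaller effect at 8 than at 4 weeks in 8 of 21 (median -0.24, turning to 0.60 with library sizes alone, camera adjusted p = 0.012; adjusted p = 0.404 with an estimated correlation).

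By edgeR, the effect differed for 4576 genes between 8 and 4 weeks (2266 higher, 2310 lower), for 6089 between 8 and 2 weeks (3151 higher, 2938 lower) and for 5479 between any ages. With library sizes alone the median of all genes stood at 0.77 and 0.66 in the first 2 of these, and the splits were 7176 against 217 and 6317 against 297. Between 4 and 2 weeks edgeR called 0 genes (1171 at an unadjusted p below 0.05), DESeq2 called 4, pool A alone 42 and the libraries of these 2 ages alone 1. Between 8 and 4 weeks pool A alone gave 1107 genes, pool B alone 2899, and labelled males alone 1995.

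Called genes were shared between ages, which have no library in common. Of the 412 genes that rose at 4 weeks 232 (56.3%) rose at 8 weeks, where 108.0 would be expected, and 22 fell. Of the 534 that fell at 4 weeks 376 (70.4%) fell at 8 weeks, where 140.6 would be expected, and 25 rose. Of the 891 that rose at 6 weeks 618 rose at 8 weeks (233.6 expected), and of the 726 that fell 622 fell (191.2 expected). Between 4 and 6 weeks 81 rises (21.9 expected) and 160 falls (23.2 expected) were shared. Of the 6 rises at 2 weeks 5 were called at 4 weeks, and of the 4 falls 3 were.

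Growth of wild-type muscle gives the background for these effects. From 2 to 4 weeks cell cycle genes fell in 24 of 26 (median -1.89, camera adjusted p = 1.37e-09; adjusted p = 0.295 with an estimated correlation). Extracellular matrix genes fell in 21 of 30 (-0.61, adjusted p = 3.01e-07; adjusted p = 0.324 with an estimated correlation), and myogenesis and regeneration genes in 12 with 1 higher of 23 (-0.66, adjusted p = 5.04e-06; adjusted p = 0.246 with an estimated correlation). Glycolysis and glycogen rose in 23 and fell in 2 of 28 (0.91, camera adjusted p = 1.01e-08; adjusted p = 0.246 with an estimated correlation). Fast fibre genes rose in 13 and fell in 1 of 17 (0.86, adjusted p = 0.00133; adjusted p = 0.505 with an estimated correlation), and complex I rose in 25 of 36 (0.38, turning to -0.11 with library sizes alone, adjusted p = 1.36e-06; adjusted p = 0.505 with an estimated correlation). From 4 to 8 weeks erythroid markers fell in 7 of 7 (-1.74, camera adjusted p = 3.72e-10; adjusted p = 0.0756 with an estimated correlation) and extracellular matrix in 21 of 30 (-0.60, adjusted p = 6.66e-12; adjusted p = 0.193 with an estimated correlation). Slow fibre genes rose in 10 of 14 (2.17, camera adjusted p = 0.000377; adjusted p = 0.528 with an estimated correlation), but without animal 36 the median was 0.64, with 4 higher and 1 lower.

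In edgeR, 8008 genes changed in wild type from 2 to 4 weeks (4052 rose, 3956 fell) and 2575 from 4 to 8 weeks (1305 rose, 1270 fell). In knockout the numbers were 6411 (3396 rose, 3015 fell) and 7457 (3865 rose, 3592 fell). With library sizes alone the splits were 360 against 7617 and 295 against 583 in wild type, and 254 against 8025 and 9825 against 458 in knockout, as the median of all genes then stood at -0.53, -0.11, -0.62 and 0.68. From 4 to 8 weeks in wild type, pool A alone gave 214 genes and labelled males alone 741, and without the rRNA-rich libraries and animal 36 the number was 1701.

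Genes of wild-type growth were then compared with the knockout effect at 8 weeks, in groups that share no library. Myh8, Myh3, Mymk, Igf2 and Myog are among the 1535 genes that fell more than 2-fold in wild type from 2 to 4 weeks. These 1535 genes had a median log2 fold change of 0.95 in the 8-week knockout, with 81.1% above 0 and 726 called higher. The 455 genes that rose more than 2-fold had a median of -0.95, with 86.2% below 0 and 303 called lower. These medians and shares hold for TMM scaling and were not computed with library sizes alone. The median of all genes at 8 weeks then moved to 0.82, so positions above or below 0 are relative to that median. Across these genes, which are not independent replicates, Spearman's rho was -0.59, and it was -0.52 without the rRNA-rich libraries. In a regrouping of the 8-week libraries, where the real value was -0.57, rho was as large in size in 5 of 100 splits. Chance could thus not be excluded for rho.

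**Figure D5:**
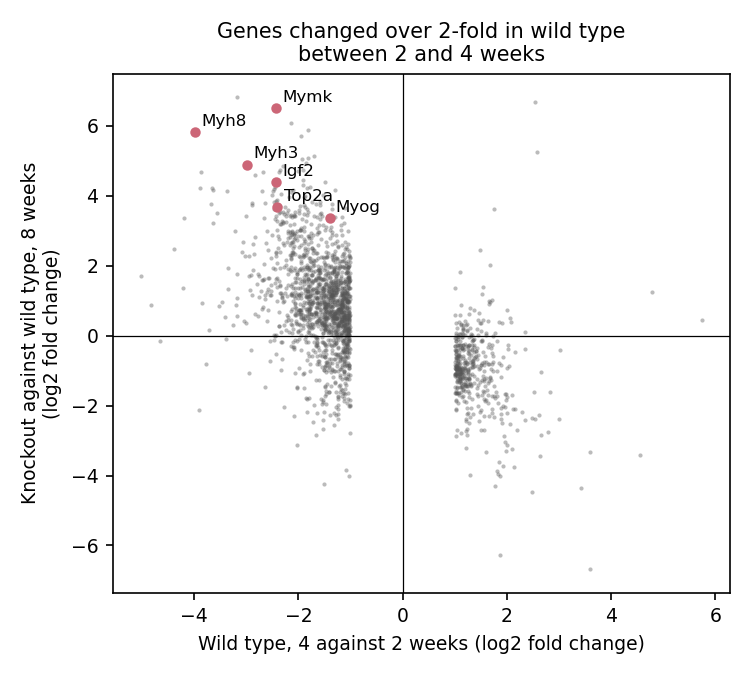
Log2 fold change of knockout against wild type at 8 weeks (vertical axis) against that of wild type at 4 weeks over 2 weeks (horizontal axis) for the 455 genes that rose and the 1535 that fell more than 2-fold, 1 point per gene. Myh8, Myh3, Mymk, Igf2, Top2a and Myog lie in the upper left, at falls with growth and rises in knockout. Both axes use TMM scaling.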

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

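The tests of the rRNA-related genes and of animal 36, and those of the Gm10800 genes other than the test of their wider family, were chosen only after the result was seen.

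Lars2, CT010467.1, Mir6236, Mir6240 and n-R5-8s1 had a median log2 fold change of -6.27 in the 8-week knockout, and wild-type animals 34 and 35 held 20.3% and 23.1% of counts in nuclear rRNA genes. Without the libraries over 5% rRNA the median was -1.10, so ribosomal RNA left in those 2 libraries may account for most of the difference. A change of the knockout muscle of that size was argued against in pool B, which holds no rRNA-rich library at 8 weeks: 0 of the 5 genes passed the threshold there, and the median was -0.88, with Lars2 at -1.20 (SE 1.27). Since a p over the threshold does not show that values did not differ, a smaller fall in the knockout stays open. Exact sharing of reads between Lars2 and CT010467.1 was argued against, as 0% of the 38-bp words of CT010467.1 occur in Lars2 transcripts. Reads with mismatches and rRNA sequence outside that annotated gene were not tested. Lars2 held 2.76% to 20.9% of counts in the 5 rRNA-rich libraries and at most 1.18% in the others, so rRNA reads counted in Lars2 stay open.

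Wild-type animal 36 at 8 weeks lay far from the other 4 wild-type animals in several lists. Its slow-fibre genes other than Myh7, Tnnt1 and Myl2 lay 2.82 log2 units above the other 8-week wild-type libraries at the median (11 of 11 above), and its fast-fibre genes 1.85 below (median -1.85, 15 of 17 below), so slow muscle tissue in the sample is a candidate explanation. A mislabelled knockout library was argued against by 182 CPM of Nampt, since the highest 8-week knockout library had 56.0. Ribosomal RNA taking most of the counts was argued against by a share of 0.314%. The design names no group that would give a biological explanation, and a sample from another wild-type animal stays open and was not tested.

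Gm10800, Gm10801 and Gm21738 were higher in the knockout at every age, at 7.24, 5.57 and 4.52 log2 units at 2 weeks and 6.67, 7.85 and 4.11 at 8 weeks. Gm10800 lay above every wild-type library in 18 of 18 knockout libraries (highest wild type 2.26 CPM, lowest knockout 11.5), so a fixed feature of the knockout animals, such as sequence in or near a transgene, is a candidate explanation, which genotype alone cannot separate from a response to loss of Nampt. For a muscle response that grows with age, 0 of the 3 genes had a larger effect at 8 than at 2 weeks past the threshold, but the differences had wide errors (Gm10801 2.27, SE 1.88), so growth stays open. For release of the wider family of genes that share read-length words, the summed level of 8 other genes gave an exact permutation p of 0.0606 at 8 weeks, where a value of 0.05 or more had been set to count against it. The sum used only the 8 genes that share most words with each of the 3. Each shares words with 12 other genes, so part of the family was left out. That limit was wrong for these counts, which ran from 0 to 16 per library, and the same sum was higher in knockout at 2 weeks (exact permutation p = 0.013) and 4 weeks (exact permutation p = 0.00433), so this cannot be told apart from the feature above.

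An animal was marked when its gap to the nearest animal of its group, divided by the whole range of the group, passed Dixon's 95% value. Chance marks about 1 in 20 groups, and 29 of 348 groups (8.33%) were marked, 6 through wild-type animal 36, 6 through knockout animal 8 and 2 through wild-type animal 3. Animal 36 lay apart in glycolysis (ratio 0.911), slow fibres (0.736), fast fibres (0.897), circadian genes (0.839), Cdh4 (0.747) and Barx2 (0.880). Knockout animal 8 at 4 weeks lay apart in nuclear rRNA share (0.975), mitochondrial share (0.929), share of the top 10 genes (0.924), TCA cycle (0.821), mitochondrially encoded mRNAs (0.712) and erythroid markers (0.794).

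In the other animals of 4 weeks, wild-type animal 3 lay apart in mitochondrial share (0.724) and mitochondrial chaperones (0.712), wild-type animal 4 in NAD synthesis (0.709) and wild-type animal 1 in fast fibres (0.720). Wild-type animal 6 lay apart in oxidative stress genes (0.819), lipid synthesis (0.746) and Mt1 (0.756), and knockout animal 7 in autophagy (0.731) and lymphocyte markers (0.972). At 2 weeks knockout animal 31 lay apart in nuclear rRNA share (0.886), knockout animal 30 in mitochondrial biogenesis (0.824) and wild-type animal 25 in neutrophil (0.682) and lymphocyte markers (0.925). At 8 weeks knockout animal 43 lay apart in Nampt (0.714), knockout animal 40 in neutrophil (0.658) and erythroid markers (0.687), and wild-type animal 35 in Myl4 (0.771).

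The knockout effect differed between ages by a test of the difference itself. It did so for 4576 genes between 8 and 4 weeks, for 6089 between 8 and 2 weeks and for 5479 between any ages. For Nampt the effect differed by -1.02 (adjusted p = 9.61e-06 in edgeR) and -1.09 (1.47e-06), with 6 of 6 knockout libraries below every wild-type library at 8 weeks. For the denervation list it differed by 1.05 between 8 and 4 weeks and by 0.95 between 8 and 2 weeks.

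Other splits of the libraries, drawn within age where the effect of knockout was tested, were counted with the real split included. For the 10 genes at 2 weeks 4 of 100 splits gave as many genes (highest other 171). The splits were not drawn within pool, and at 2 weeks 4 of 5 knockout and 2 of 6 wild-type libraries were of pool A. In edgeR 812 genes had an unadjusted p below 0.05 at 2 weeks where 836.4 would be expected by chance. Chance was therefore not excluded for that count. For the 946 genes at 4 weeks 2 of 100 splits gave as many (highest other 1156), which argues against chance but does not exclude it. Chance could be excluded for the 8790 at 8 weeks (1 of 100, highest other 6078). The split with 1156 genes at 4 weeks joined animals 6, 7, 8, 11 and 12, which swaps wild-type animal 6 for knockout animal 10, and points to a structure of the samples there. Knockout animals 7, 8 and 12 had a mean log2 CPM of macrophage markers of 3.29 to 4.61, against 1.93 and 2.06 in knockout animals 10 and 11 and 1.68 to 2.46 in wild type. The split with 171 genes at 2 weeks called several times the real count and points to a structure of the samples. It joined animals 23, 25, 28, 29 and 31, and the last 4 had 1.57 to 3.39 CPM of Cd79a and 21.9 to 30.3 CPM of Ptprc, against at most 0.376 and 6.45 in the other 2-week libraries. For the differences between ages only the real split gave as many genes (1 of 100 in each). The counts were 4576 between 8 and 4 weeks (highest other 3956), 6089 between 8 and 2 weeks (highest other 2249) and 5479 between any ages (highest other 4044). These splits shuffle genotype within every age and so remove any knockout effect at all ages. They cannot tell an effect that differs between ages from an equal one, and decide nothing on that difference. Between 4 and 2 weeks edgeR called 0 genes (1171 at an unadjusted p below 0.05, and 4 by DESeq2), so every split gives as many and the count of splits (100 of 100, highest other 207) decides nothing. For ages within wild type chance could be excluded from 2 to 4 weeks (8008, 1 of 100, highest other 4400) and from 4 to 8 weeks (2575, 1 of 100, highest other 1072). The same held in knockout from 2 to 4 weeks (6411, 1 of 100, highest other 2338) and from 4 to 8 weeks (7457, 1 of 100, highest other 7324).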

How the results depend on the processing

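The alternatives without rRNA-rich libraries, without these and animal 36, without libraries that differ from their sex label, and with sex taken from Xist and Ddx3y were tests chosen only after the result was seen. Of 152 counts of genes under alternatives other than single omissions, 108 lay within 1.5 times the reported count and 44 did not. Of 3730 values of named genes 3135 kept direction and call, 577 lost the call and 18 changed sign. Of 388 values of called lists 314 counted as kept, 69 lost the call and 5 changed sign. For each pool alone only the sign of the list median was compared, as camera was not run there, so a kept value there is no kept call. Medians with library sizes alone, where several called lists turned sign, were not counted. With an estimated correlation no called list kept its call (lowest camera adjusted p = 0.152, denervation list at 8 weeks). Except where stated, the cause was not tested. No paired analysis was possible because each number belongs to 1 animal and the groups share none. Depth limited the tests to the 16728 of 50686 genes that passed the filter on counts.

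With library sizes alone the counts were 120 at 4 weeks, 330 at 6 weeks, 7393 for 8 against 4 weeks and 878 for wild type from 4 to 8 weeks. No filter gave 562 at 4 weeks and 1067 at 6 weeks, with more genes tested. A term for the labelled sex, without the 2-week libraries, gave 97 at 4 weeks, 615 at 6 weeks and 1435 for wild type from 4 to 8 weeks. Sex taken from Xist and Ddx3y over all ages gave 929 at 4 weeks, 1535 at 6 weeks and 2659 for wild type from 4 to 8 weeks. Males by label (animals 12 and 42, with high Xist, among them), with fewer samples, gave 12 at 4 weeks, 1995 for 8 against 4 weeks, 741 for wild type and 4794 for knockout from 4 to 8 weeks. Pool A alone, with fewer samples, gave 1 at 2 weeks, 4286 at 8 weeks, 42, 1107, 2121 and 1505 for the differences (4 against 2, 8 against 4, 8 against 2, any), 3213 and 214 for wild type and 3607 and 2442 for knockout (2 to 4, 4 to 8 weeks). Its 8-week wild type was the rRNA-rich animals 34 and 35 alone. Pool B alone gave 2 at 2 weeks, 9 at 4 weeks, 2899, 1869 and 2006 for the last 3 differences, 1286 for wild type from 4 to 8 weeks and 2008 for knockout from 2 to 4 weeks. The compared groups alone gave 177 at 2 weeks, 194 at 4 weeks, 584 at 6 weeks, 1 and 3003 for the first 2 differences, and 1427 and 4668 from 4 to 8 weeks in wild type and knockout. DESeq2 gave 20 at 2 weeks and 4 for 4 against 2 weeks. Without rRNA-rich libraries 303 were called at 4 weeks, without these and animal 36 527 at 4 weeks, 2737 at 6 weeks and 1701 for wild type from 4 to 8 weeks, and without sex mismatches 474 at 4 weeks.

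Nampt at 2 weeks lost its call with library sizes alone (-0.79), in pool A (-0.73) and in pool B (-1.09). The rank correlation of the maturation genes moved from -0.59 to -0.66 with no fold threshold, -0.54 with RLE factors and -0.52 without rRNA-rich libraries. In pool B at 2 weeks list medians changed sign for complex I (-0.066), complexes III to V (-0.049), fatty acid oxidation (-0.085) and macrophage markers (0.071). At 4 weeks the median of complex I changed sign in pool B (0.00080). Without knockout animal 8 the camera test of complex I at 4 weeks changed direction (median -0.00305, in a range from -0.17 over the omissions). In pool B the differences of CT010467.1 (2.35) and Mir6236 (0.13) between 8 and 4 weeks changed sign. With library sizes alone at 8 weeks the median of all genes moved to 0.82, and 185 of 527 called list members (35.1%) changed sign. Among the genes whose values were counted above, sign changed for Sirt2 (0.10), Gyg (0.081), Dld (0.15), Sdha (0.16), Ndufa8 (0.10), Uqcrb (0.10), Atp5j (0.17), Atp5c1 (0.12), Lonp1 (0.21), Hspd1 (0.37), Hspa9 (0.36), Spg7 (0.28), Ulk2 (0.042), Kdr (0.071), Fabp4 (0.093) and Ei24 (0.16).

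Leaving out each library in turn gave 5 (without wild-type animal 21) to 10 genes at 2 weeks, 345 (without knockout 7) to 1598 (without knockout 10) at 4 weeks, 244 (without wild-type 16) to 1174 (without knockout 19) at 6 weeks and 7862 to 8992 at 8 weeks. At 4 weeks the counts without knockout 8, knockout 12, wild-type 1 and wild-type 2 were 472, 548, 505 and 601, and at 6 weeks those without wild-type 17 and knockout 20 were 522 and 286. At 6 weeks an omission leaves 1 library in a group, assumed to vary like the other groups. The ranges were 0 to 1 (1 without knockout 11) for the difference of 4 against 2 weeks, 3781 to 5154 for 8 against 4, 5404 to 6594 for 8 against 2 and 4690 to 5920 for any ages. They were 7343 to 7774 and 2025 to 2610 in wild type, and 5309 to 6481 and 6517 to 8061 in knockout, from 2 to 4 and 4 to 8 weeks.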

Other observations

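The tests of a delay and of the regrouped maturation genes were chosen only after the result was seen.

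Nmrk2, the nicotinamide riboside kinase, was higher in knockout by 4.03 log2 units (SE 0.44) at 4 weeks and by 1.98 (SE 0.42) at 8 weeks. Amd1, an enzyme of polyamine synthesis, fell by 4.03 at 6 weeks and by 3.97 at 8 weeks. Ppif, cyclophilin D of the mitochondrial permeability pore, rose by 0.86 (SE 0.10) at 4 weeks, and the mitochondrial fusion gene Mfn1 fell by 0.93 (SE 0.14) at 6 weeks and by 1.33 (SE 0.09) at 8 weeks. The ADP/ATP carrier Slc25a5 rose by 1.36 (SE 0.16) at 8 weeks.

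Genes that fall in wild type from 2 to 4 weeks were higher in the 8-week knockout, and a delay of muscle growth already present at 4 weeks is a hypothesis for this. It would place the extracellular matrix and cell cycle lists above 0 at 4 weeks, but the higher of their 2 medians was -0.12. The extracellular matrix list was called lower at 4 weeks (median -0.17, camera adjusted p = 0.0233; adjusted p = 0.888 with an estimated correlation), but 2 of 5 knockout libraries lay above the wild-type mean and its median was -0.045 in pool B. That call was lost without any of wild-type animals 2 and 6 and knockout animals 7 and 10. The cell cycle list was not called (camera adjusted p = 0.247), so a small delay could not be excluded for these 2 lists. Myogenesis and regeneration genes had a mean log2 CPM of 5.23 to 5.43 in knockout at 2 weeks. At 4 weeks it was 3.87 to 4.42 (wild type 3.82 to 4.45), and at 8 weeks 4.62 to 5.66. A fall with wild type and a later rise argue against a delay for this list. Knockout ranges at 4 and 8 weeks overlapped for cell cycle (0.45 to 2.97, 2.33 to 3.98) and extracellular matrix (6.63 to 7.54, 7.26 to 8.18). When the 8-week libraries were regrouped, rho was as large in size in 5 of 100 splits (real value -0.57, highest other 0.603), so chance could not be excluded for rho. The gap between the medians of falling and rising genes was 1.81, reached in 1 of 100 splits (highest other 1.62).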
